A study of Oryza sativa with 3 samples.

How the data were processed

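ChIP-seq with an anti-Flag antibody was carried out on seedlings of rice carrying a 35S-driven Flag-tagged ngr2 in the WYJ7-dep1-1 background. Per the labels' protocols, the tissue was fixed with formaldehyde, the chromatin was sonicated to fragments of about 500 bp, and library fragments of 100 to 500 bp were selected on a gel. The 3 samples have the same labels for genotype, tissue and antibody and were treated as replicates of 1 group. The labels give no replicate numbers in these fields, so the samples were numbered 1 to 3 in the order of their records. The titles of replicates 1 and 2 name the Flag tag and that of replicate 3 does not. Replicate 3 was kept because its other labels are the same, and the mean share of overlapping regions, the consensus count and the dense loci were repeated without it.

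The authors deposited 1 list of regions per sample, each with 5 columns: chromosome, start, end, a peak name and a score. The peak names in the deposited lists name MACS, a peak caller. The version, its settings, the control library, the aligner, the read filters and the genome build are not given in the sources used here. The score column deposited by the authors has no unit in the file. Its values started just above 50 (lowest values 50.03, 50.04 and 50.02) and stopped at 3100 in each list, which 3, 10 and 3 regions reached. Scores from a peak caller depend on sequencing depth and on the control, so they were not used to compare levels between samples. They ranked regions within a list, and their mean over samples chose the regions named, with the mean percentile within each list as an alternative added after seeing the data. A threshold on the score, and a control shared by the samples, would both shape which regions are listed. Each list was deposited for 1 sample, and the reads behind it are not given in the sources used here.

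Starts were converted from the BED convention to 1-based positions. Regions of different samples were called shared when they overlapped by at least 1 bp, merged into 1 region where they overlapped, and called consensus regions when at least 2 samples held them. No lists were identical, with 31, 13 and 36 identical intervals between replicates 1 and 2, 1 and 3, and 2 and 3. Loci were made by chaining merged regions over gaps of up to 20 kb, and a locus with at least 10 merged regions was called dense. This definition was chosen after the data had been seen. The overlap and consensus definitions, the tests of sharing against random placement and the rule for the regions named were set before the data were examined. That rule took the 25 consensus regions with the highest mean score over the samples that held them.

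Chance was estimated by placing each region of a list at random on its own chromosome, 10000 times, with 2-sided permutation p-values and Benjamini-Hochberg adjustment. The genome sequence was not used, so the length of a chromosome was taken as the largest region end in the 3 lists, 363 Mb in all. Gaps and repeats in the assembly were not masked. A second null rotated each list along its chromosomes, which keeps the spacing of neighbours. Intervals on shares are exact Clopper-Pearson 95% intervals. Sharing of regions above and below the median score was compared with Fisher's exact test. The overlap code was tested on simulated lists of 440 regions, made for the comparison of replicate 1 with replicate 2. With 10.0% of regions planted as shared, 10.4 ± 0.27% were recovered (SD over 20 simulated lists). With 50.0% planted, 50.1 ± 0.16% were recovered, and with none planted 0 of 20 lists gave a p below 0.05. The simulated lists were drawn by the same random placement as the null, without clustering. They test the code and not how the null behaves for clustered lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

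The alternatives were a reciprocal overlap of 50%, a gap of up to 500 bp, the regions above each list's median score alone, presence in all 3 samples, and leaving out each replicate in turn. The position of regions relative to genes, the enrichment of gene lists (nitrogen, carbon and hormone genes among them), the binding motifs and the placement of regions within promoters were planned. They were not analysed here, because they need the sequence or annotation of the build the lists use. For the same reason GRF4 and DEP1, which were to be named whatever their values, have no value here.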

Results

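Chromatin immunoprecipitation with an anti-Flag antibody, followed by sequencing (ChIP-seq), was used to map where a Flag-tagged ngr2 protein sits on the rice genome. The tagged protein was driven by the 35S promoter, a strong plant promoter, in rice plants of the WYJ7-dep1-1 background, and whole seedlings were sampled at 2 weeks of age. As background, ngr2 is known as an allele of GRF4, which encodes a growth-regulating factor, a plant-specific class of transcription factor. All 3 samples carried the same genotype, tissue and antibody labels and formed 1 group, so the design gives no contrast between conditions. The question the data can answer is which regions were enriched in the seedlings, and how far the samples shared them. The labels do not say that the samples came from separate plants or cultures, so the spread between them may be technical.

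The deposited lists held 440 regions in replicate 1, 620 in replicate 2 and 439 in replicate 3, which is 500 ± 104 regions per sample (SD, n = 3). Together the regions of a sample covered 227 ± 25.1 kb (SD, n = 3). Their median length was 320.5 bp in replicate 1, 246.5 bp in replicate 2 and 260.0 bp in replicate 3. The number of reads behind each list is not given in the sources used here, so the depth is unknown and no region can be called absent from a sample. The regions were compared with random positions because no input or untagged library was among the samples analysed here. Positions are printed 1-based in the coordinates of the deposited lists, whose genome build is not given in the sources used here. Genes were therefore not assigned to the regions.

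The samples shared a large part of their regions. Of the regions of replicate 1, 335 of 440 (76.1%, exact 95% interval 71.9 to 80.0%) overlapped a region of replicate 2 by at least 1 bp, and 209 (47.5%, 42.8 to 52.3%) overlapped one of replicate 3. Of the regions of replicate 2, 348 of 620 (56.1%, 52.1 to 60.1%) overlapped replicate 1 and 285 (46.0%, 42.0 to 49.98%) overlapped replicate 3. Of the regions of replicate 3, 213 of 439 (48.5%, 43.8 to 53.3%) overlapped replicate 1 and 283 (64.5%, 59.8 to 68.9%) overlapped replicate 2. The intervals cover counting error only and treat regions as independent, although many were neighbours. When the same regions were placed at random on their chromosomes, the mean overlap of the 6 comparisons was between 0.200% and 0.279%. No random placement in 10000 exceeded 1.59%. Rotating whole lists along their chromosomes, which keeps neighbours together, gave mean overlaps of 0.191% to 0.274%, and its highest value per comparison lay between 16.1% and 20.7%. Each of the 6 shares was above chance under both (two-sided permutation tests, adjusted p = 0.0002 over the 6 comparisons, the smallest the placements can give). These tests compare the lists with random positions only. Without an input or untagged library they cannot tell shared binding from regions that recur for another reason. Counted in bases, the Jaccard index (shared length over combined length) was 0.684 for replicates 1 and 2, 0.544 for replicates 1 and 3 and 0.565 for replicates 2 and 3.

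Merging overlapping regions of the 3 samples gave 853 regions, of which 390 were held by at least 2 samples and are called consensus regions here. Of these, 199 were held by all 3 samples, 121 by replicates 1 and 2 alone and 70 by replicates 2 and 3 alone. No merged region was held by replicates 1 and 3 without replicate 2. A single sample held 105 regions in replicate 1, 202 in replicate 2 and 156 in replicate 3. Random placement gave 4.30 consensus regions on average and at most 14 in 10000 placements, and rotation gave 2.57 on average and at most 60 (permutation tests, two-sided p = 0.0002 for each, the smallest they can give). The count rests in part on replicate 2. Without it, 202 regions were shared by the remaining samples, against 274 without replicate 1 and 325 without replicate 3.

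**Figure D1:**
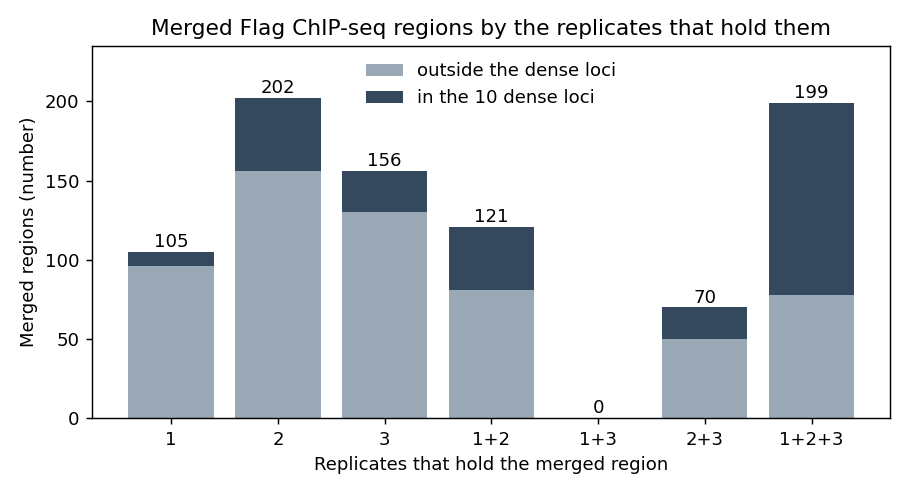
Number of merged regions (vertical axis) held by each combination of the 3 replicates (horizontal axis), split into those inside and outside the 10 dense loci described in the text. All 3 replicates held 199 regions, and the combination of replicates 1 and 3 alone held 0.

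Regions with high peak scores were shared more often than those with low scores. The score is the value the authors' peak caller gave each region. It was used here to rank regions within a list. Of the 220 regions of replicate 1 above its median score, 219 (99.5%) were found in replicate 2, against 116 of the 220 others (52.7%). In replicate 2, 256 of 310 regions above the median score (82.6%) were found in replicate 1, against 92 of 310 (29.7%). In replicate 3, 183 of 219 (83.6%) were found in replicate 2, against 100 of 220 (45.5%). Replicate 3 held 70.5% of the higher-scoring regions of replicate 1 against 24.5% of the others, and 69.0% against 22.9% of those of replicate 2. Replicate 1 held 68.5% of the higher-scoring regions of replicate 3 against 28.6% of the others. All 6 such comparisons passed Fisher's exact test (two-sided, largest adjusted p = 4e-17 over the 6), which treats regions as independent. Across overlapping pairs of regions, the Spearman correlation of the scores was 0.71 for replicates 1 and 2, 0.61 for replicates 1 and 3 and 0.80 for replicates 2 and 3. These correlations are across regions, which are not independent replicates.

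Ranked by mean score over the samples that held them, a rule set before the data were examined, the first 25 consensus regions lay at 17 loci on 10 chromosomes. They had a median length of 745 bp, and 17 of them were held by all 3 samples. The other 8 were held by replicates 1 and 2 and were not listed for replicate 3. The rule averages scores of lists whose scales may differ, over different samples for different regions, and 10 of the 25 have a score at the limit of 3100. Ranked by mean percentile within each list, a choice made after seeing the data, 20 of the 25 remained, and 14 of the new 25 were held by all 3 samples. Of the regions ranked by mean score, only 2 reached the score of 3100, at which the scores stop, in all 3 samples. They were chromosome 11 from 12122367 to 12123224 (858 bp) and chromosome 3 from 28512781 to 28514793 (2013 bp). Beside the former, chromosome 11 also held top regions from 12123271 to 12123487, from 12266494 to 12266700 and from 12351983 to 12352909, all in all 3 samples. On chromosome 2, 3 top regions lay between 28863564 and 28867198, again in all 3 samples. Single top regions held by all 3 samples lay on chromosome 3 from 27419743 to 27420864 and from 32645970 to 32646978. Others lay on chromosome 8 from 25274712 to 25275754 and on chromosome 9 from 16414615 to 16415716. The remaining 5 top regions in all 3 samples lay on chromosome 12 between 26307950 and 26315525. Their scores stood at percentiles 66.0 to 85.6 of replicate 1, 95.9 to 99.2 of replicate 2 and 97.8 to 99.7 of replicate 3. Most of these chromosome 12 regions, and the chromosome 3 region from 27419743, were left out by the ranking by percentile.

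The 8 top regions of replicates 1 and 2 that replicate 3 did not list were spread over 7 loci. A region of chromosome 2 from 33442729 to 33443844 had a score of 3100 in both samples. A region of chromosome 5 from 860177 to 862491, the longest of the 25 at 2315 bp, scored 2831 in replicate 1 and 3100 in replicate 2. The others lay on chromosome 1 from 38382380 to 38382731, on chromosome 3 from 22844958 to 22845554, on chromosome 4 from 33630723 to 33632215 and on chromosome 6 from 2808235 to 2808708. Neighbouring regions from 197647 to 198351 and from 198448 to 199060 on chromosome 11 completed the set. Their scores lay at or above percentile 93.5 of replicate 1 and percentile 96.4 of replicate 2, counting ties by mid-rank. Of the 220 regions of replicate 1 above its median score, 65 overlapped no region of replicate 3.

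**Figure D2:**
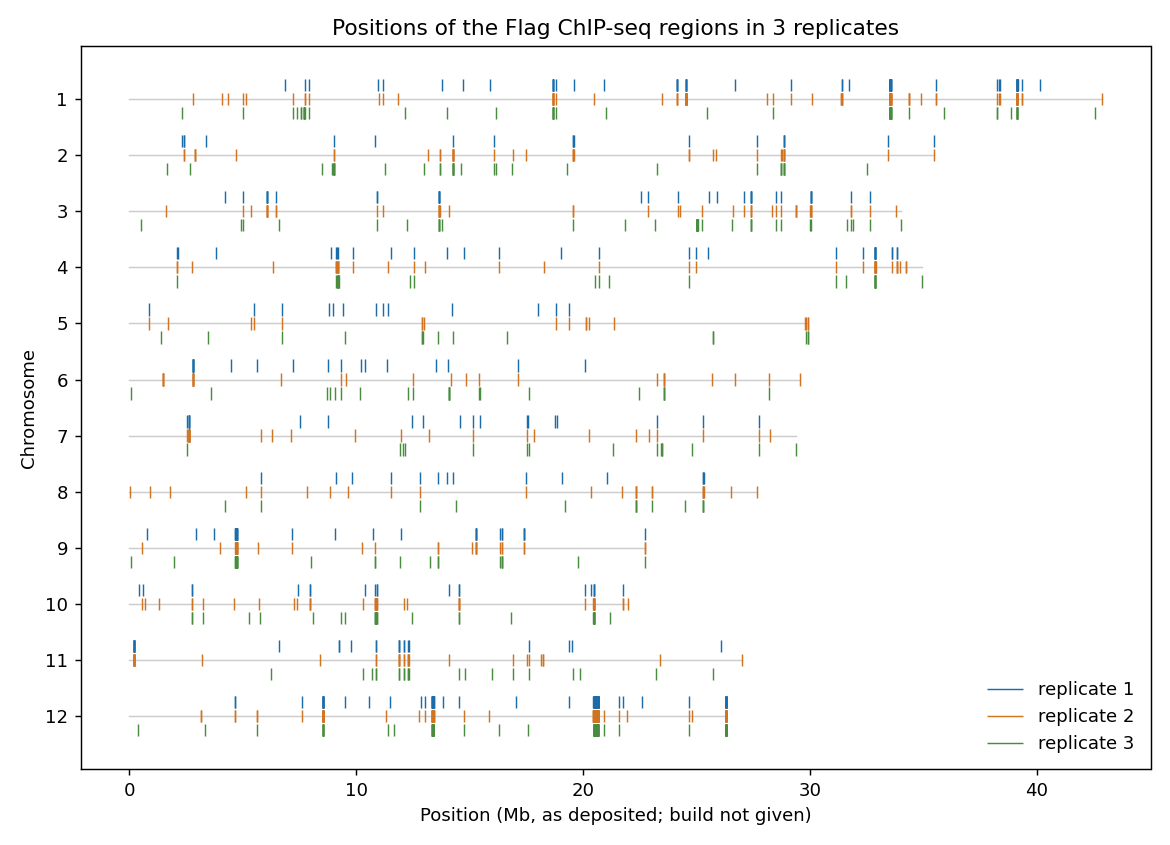
Midpoints of the deposited regions along the 12 chromosomes (horizontal axis in Mb, vertical axis the chromosome), with 1 row of ticks per replicate. Regions lay on every chromosome, and chromosome 12 held 143, 186 and 129 of the regions of replicates 1, 2 and 3.

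The regions were unevenly spread. Chromosome 12 held 30.6 ± 1.65% (SD, n = 3) of a sample's regions, although it made up 7.26% of the length over which regions were placed. The excess came from a few places. Chaining merged regions over gaps of up to 20 kb gave 442 loci, of which 363 held a single merged region, and chromosome 12 held 35 of the 442 loci (7.92%). There were 10 dense loci with at least 10 merged regions each, on 4 chromosomes, 5 of them on chromosome 12. They spanned 414 kb, or 0.114% of the length, and held 39.7 ± 1.08% (SD, n = 3) of a sample's regions and 181 of the 390 consensus regions (46.4%). Of the 140 consensus regions on chromosome 12, 9 lay outside them. Up to 55 merged regions started within 100 kb, against at most 12 in 10000 random placements (permutation test, two-sided p = 0.0002, the smallest they can give).

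Of the dense loci, 8 were found in all 3 samples. A pair of them lay close together on chromosome 12. The locus from 20460672 to 20577548 (117 kb) held 40.0 ± 6.24 regions per sample, which covered 35.7 ± 1.37% of it (SD, n = 3). The locus from 20610555 to 20668751 (58.2 kb) held 38.3 ± 6.66 regions per sample and was covered to 46.6 ± 2.74% (SD, n = 3). Another locus of chromosome 12, from 13342310 to 13419264 (77.0 kb), held 34.3 ± 10.7 regions and was covered to 14.8 ± 3.14% (SD, n = 3). The locus of chromosome 12 from 26307504 to 26315525 was short (8.02 kb) and densely covered, at 55.1 ± 6.98%, and that from 8530011 to 8557290 was covered to 31.7 ± 2.61% (SD, n = 3). On chromosome 9 the locus from 4678563 to 4732505 held 21.3 ± 1.53 regions and was covered to 34.2 ± 0.521% (SD, n = 3). On chromosome 1 the locus from 33516208 to 33553435 held 16.0 ± 1.73 regions and was covered to 36.8 ± 0.977% (SD, n = 3). A further locus of chromosome 1, from 39111501 to 39128762, held 10.3 ± 3.06 regions (SD, n = 3).

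**Figure D3:**
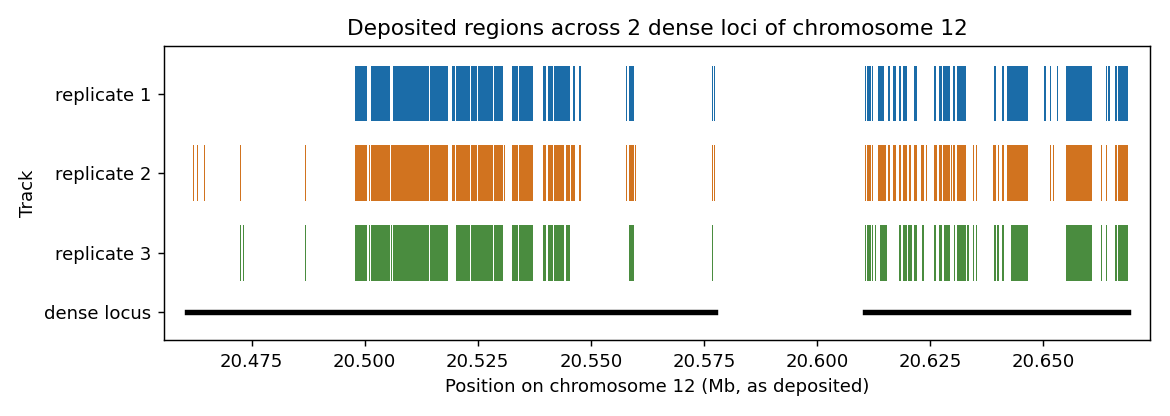
Deposited regions (filled blocks, to scale) along chromosome 12 in each replicate, with position in Mb on the horizontal axis and black bars for the 2 dense loci. The covered share of the left locus was 35.5, 37.2 and 34.5% in replicates 1, 2 and 3, and that of the right locus 45.3, 49.8 and 44.8%.

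Outside the dense loci, 209 consensus regions were found, and 78 of them (37.3%) were held by all 3 samples, against 121 of 181 (66.9%) inside. With the regions of the dense loci left out, the mean overlap over the 6 comparisons was 42.8%, against 56.5% with them. Random placement of the remaining regions gave at most 0.575%, and rotation of the remaining lists at most 1.69%.

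Some loci had regions in the lists of part of the samples only. At 7 loci at least 1 sample listed 5 or more regions and at least 1 other listed none. Replicate 3 alone listed 15 regions on chromosome 3 from 25043037 to 25051111, covering 52.9% of the locus, and 5 regions on chromosome 1 from 7687274 to 7693420. Replicates 1 and 2 listed regions at the other 5 loci, where replicate 3 listed none. These were chromosome 1 from 24535507 to 24545264 (5 and 16 regions), chromosome 11 from 194336 to 199060 (8 and 11), chromosome 3 from 6053106 to 6061341 (4 and 5), chromosome 6 from 2806926 to 2812863 (6 and 6) and chromosome 7 from 2643812 to 2647567 (4 and 9). At all 7 loci replicate 3 differed from replicates 1 and 2, and its title is the one that does not name the Flag tag. It did not stand apart in every measure. The Jaccard index was highest for replicates 1 and 2 (0.684), but the Spearman correlation of scores was highest for replicates 2 and 3 (0.80). The counts at the 7 loci are from single lists and were not tested.

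Part of the overlapping pairs also coincided at a boundary to within 1 bp. In replicates 1 and 2, 149 of 358 overlapping pairs (41.6%) started within 1 bp of each other, and 133 (37.2%) ended within 1 bp. In replicates 1 and 3 the starts of 111 of 220 pairs (50.5%) lay within 1 bp, and in replicates 2 and 3 those of 147 of 294 pairs (50%). Starts 2 to 10 bp apart were found in 57, 25 and 51 pairs. Inside the dense loci the share of starts within 1 bp was 63.5, 65.2 and 59.2% in these pairs of replicates, and outside them it was 20.0, 27.1 and 39.4%.

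**Figure D4:**
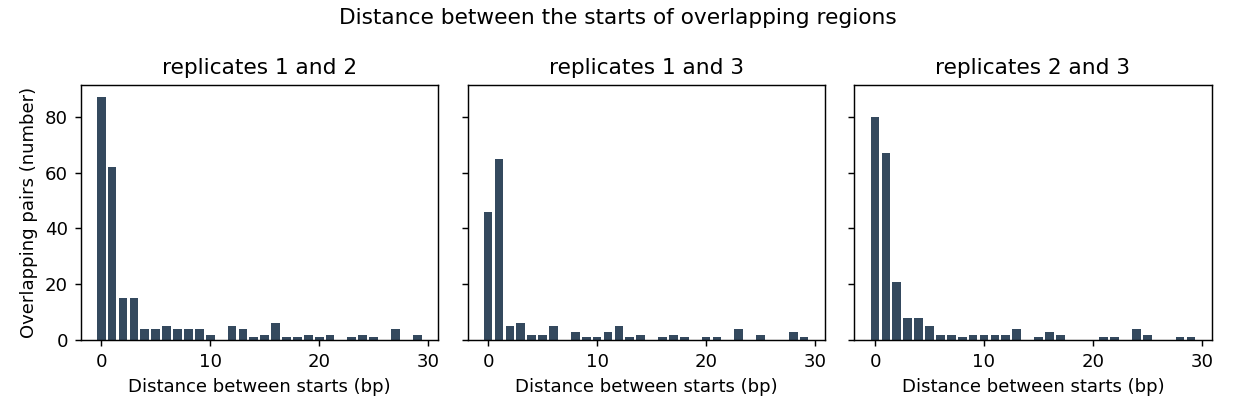
Number of overlapping pairs of regions (vertical axis) by the distance between their starts in bp (horizontal axis, distances under 30 bp), for each pair of replicates. The counts at 0 bp were 87, 46 and 80, and those at 1 bp were 62, 65 and 67, in replicates 1 and 2, 1 and 3, and 2 and 3.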

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

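Of 75 values computed under alternative settings, 59 kept their side of the threshold or stayed within the limits set for them, and none changed direction. All 45 alternatives for the shared regions stayed above random placement or rotation at p below 0.05. They are overlapping shares and their means, not separate checks. The mean share under random placement was at most 0.349% in any setting, so this outcome adds little. The observed mean share ranged from 48.0% to 66.1% when 1 replicate was left out, and lists rotated along their chromosomes gave at most 6.58%. The alternatives that leave out the dense loci, rotate the lists, rank by percentile or join regions for the consensus count were chosen after the data had been seen, as were all results on dense loci and on regions of replicates 1 and 3 without 2. The consensus count of 390 was 199 when all 3 samples were required, 237 among regions above the median score, 209 outside the dense loci and 242 when regions within 500 bp were joined. Each of these settings demands more samples, tests fewer regions or joins regions by construction. Leaving out 1 replicate gave 202 to 325 regions, lowest without replicate 2. The count of 10 dense loci became 23 with a minimum of 5 regions and 4 with a minimum of 20, and ranged from 9 to 11 when 1 replicate was left out. The 46.4% of consensus regions in dense loci became 41.5% with a gap of 10 kb, 50% with 50 kb, 63.6% with a minimum of 5 regions, 32.8% with 20 and 45.1% above the median score. It ranged from 50.8% to 61.4% when 1 replicate was left out. The absence of regions held by replicates 1 and 3 without 2 became 2 regions above the median score, because regions of replicate 2 were dropped. The placement of regions within promoters and gene bodies, and the gene and motif alternatives, were not run. No paired analysis was possible because the samples form a single group. Read depth is unknown, which limits any statement that a region is missing from a sample.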

Other observations

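All tests in this part, of shared boundaries, dense loci and missing regions, were chosen after the lists had been seen.

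The coincidence of boundaries was set against an even spread of the distances between starts. With an even spread up to 10 bp, the pairs with starts 2 to 10 bp apart would predict 4.17 pairs within 1 bp in replicates 1 and 3. The upper 95% Poisson limit was 9, and 111 were found. The limits for replicates 1 and 2 and for 2 and 3 were 16 and 15, against 149 and 147 pairs. These values argue against an even spread. They do not decide whether boundaries were placed independently, because independently placed boundaries of the same site may also lie mostly close together. The limit also treats neighbouring pairs as independent. With dense loci defined by at least 10 merged regions, the coincidence was not confined to them. The lowest share outside them was 20.0% (exact 95% interval 14.4 to 26.6%). The interval treats pairs as independent, and the share was not recomputed without smaller clusters of regions. A boundary set by something common to the lists, such as a shared control or the limits of alignable sequence, may account for it and was not tested.

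The dense loci are a place to look at the read coverage. Chance clustering is argued against by the 55 merged regions within 100 kb, against at most 12 at random. For the 8 dense loci listed in all 3 samples, a candidate explanation is a difference in DNA copy number or mappability between the ChIP libraries and their control. Regions covered a median of 34.97% of these 8 loci, which does not decide between this and clustered binding, because the control coverage was not used here. The other dense loci, on chromosome 3 from 25043037 (0, 0 and 15 regions in replicates 1, 2 and 3) and on chromosome 1 from 24535507 (5, 16 and 0), did not recur in every list, and no biological explanation was tested, since the design has a single group.

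Replicate 2 held each of the 199 merged regions that replicates 1 and 3 shared (100%, exact 95% interval 98.2 to 100%), whereas replicate 3 held 62.2% of those shared by 1 and 2, and replicate 1 held 74.0% of those shared by 2 and 3. Independent detection within score quartiles of replicate 1 would leave 20.2 regions in 1 and 3 without 2 (95% range 15 to 26). Counted by locus it would leave 9.51 (6 to 13). Within quartiles of replicate 3 it would leave 53.3 regions (46 to 61) or 21.7 loci (17 to 26). The 0 found argues against independence within quartiles. Quartiles are coarse, and the stronger regions within a quartile may be listed more often in both other samples. Independence given the strength of each region was therefore not tested. Whether replicate 2 was deeper or more strongly enriched than replicate 1 stays open, because the read counts are unknown. Regions of replicate 1 missing from 2 had a median score of 54.4 against 112 for those in both. Those of replicate 2 missing from 1 also had a lower median than those in both (62.1 against 156). The losses were not symmetric. Above each list's median score, 1 of 220 regions of replicate 1 was missing from 2, and 54 of 310 regions of replicate 2 were missing from 1. A list of replicate 2 made from the pooled reads of the others is argued against by replicate 3 only. In replicate 3, 20 of 91 regions that scored over 200, up to 1133 and at 8 loci, were missing from replicate 2. In replicate 1, 0 of 101 regions that scored over 200 were missing from replicate 2.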
